A study of Mus musculus and synthetic construct with 32 samples.

How the data were processed

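Total RNA of Ythdc2 knockout and control mice was sequenced from testes at P8 and P12 and from ovaries at P0, in 14 libraries made with a stranded kit that removes ribosomal RNA. For m6A, polyadenylated testis RNA was fragmented and immunoprecipitated beside input, in 10 libraries. RNA Bind-N-Seq took 8 libraries of random RNAs with a central m6A, bound to the YTH domain of human YTHDC2 or to beads alone. Per the labels' protocols, the small RNA kit served both the m6A and the Bind-N-Seq libraries, and there were 2 knockout lines, one without exon 7 and one with stop codons in it. The labels do not tell which line a library came from, and counts over the whole gene do not check a lesion in a single exon.

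Each mouse file was a table of the authors' own comparisons, with a mean normalized count (a signal over all libraries of the table, not a value per library), log2 fold changes and adjusted p-values, per the file headers. The fold changes are log2 ratios between groups as the authors estimated them, and they appear drawn toward 0 compared with raw ratios. In the heterozygote against the wild type at P8, 1 library each, the largest of 15592 exon folds was 0.740 in size. How strongly folds were drawn toward 0 can differ between tables, so their sizes are not strictly comparable across tables. The Bind-N-Seq file gave, per the file headers, a linear fold ratio of YTH domain over bead control and an unadjusted p-value for each of 65536 9-mers with A in the middle. The submitters' processing notes name the mm10 genome and DESeq2 for the mouse tables and cutadapt for the ovary and the Bind-N-Seq libraries, and their versions, the aligner, the counting and the annotation are not given in the sources used here. Features were exons, introns, repeats and miRNAs, each in sense and antisense. Columns of the P8 and P12 total RNA tables carry the words IP and input in the file headers, although the labels list only total RNA for them, and they were read as knockout over control. The authors' folds of genes with few counts lay close to 0. In P12 testis their SD across genes was 0.0418 at mean counts below 10 and 0.139 above 1000, which limits what the folds of low genes show, and no pseudocount was added here. Within the Bind-N-Seq file, 8 columns of values per library matched no label and were not used.

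Groups were taken from the labels. The design had planned models of counts per library, with a pooled control at P8. The tables hold no values per library, so the authors' adjusted p-values were used in their place, with 0.05 as the threshold, and no SD, no interaction of age with genotype and no other split of the samples could be computed. The authors' tables used here hold adjusted p only, so counts at an unadjusted p are not given. At P8 the wild type was taken as the main control after spermatid transcripts were seen in the heterozygous library, and the comparison with the heterozygote is given beside it. Both share the 2 knockout libraries. The design's m6A set was to come from P12. Within each feature type of the m6A table, the values were sorted by adjusted p in each age's columns separately. At P12 2911 features without a fold had a mean count above 0, and at P20 2823, against 0 at P8, and across 8040 genes Spearman's rho between exon and intron folds was 0.22 at P8, 0.01 at P12 and near 0 at P20. So the P8 columns alone were matched to gene names, the m6A set and the named m6A genes come from P8, and P12 and P20 give counts of features only. P8 rests on 1 immunoprecipitate and 1 input, with the spread borrowed by the authors, and no replicate can check it. These choices, the floor on mean counts, the tests by chromosome and the shuffles in windows of 5 Mb were made after the data were examined, while the gene lists, the thresholds and the rule for named genes were fixed before.

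Gene names were matched to RefSeq genes of GRCm38 for 19970 of 20142 names at P8, 20048 of 20215 at P12 and 19333 of 19463 in ovary. Gene lists were tested on sense exons with a mean normalized count of at least 10, which left 15592 genes at P8, 15608 at P12 and 14606 in ovary. The 17 fixed lists covered meiotic entry and prophase I, mitotic cell cycle, undifferentiated and differentiating spermatogonia, germ cell and piRNA pathway, later spermatocytes and spermatids, Sertoli cells, Leydig cells, peritubular and stromal cells, macrophages, endothelium, erythroid cells, p53 response, oocytes, pregranulosa, m6A writers, erasers and readers, and cytoplasmic RNA decay. Each list was compared with all other genes on the authors' folds by limma's cameraPR with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation was not possible, since it needs values per library. As a second test, each median was set against 10000 random lists matched in 20 strata of mean count (two-sided, seed 20). Members were counted as rising or falling at adjusted p below 0.05 over all genes, and those without an adjusted p as not passing. They were also counted when adjusted over the list alone. For this, unadjusted p-values were approximated from the authors' adjusted p, as if all features of a table had been adjusted together. In the m6A table at P8, 866 of 1039 sense miRNAs but 1709 of 19867 antisense exons had an adjusted p. Feature types were thus probably adjusted separately, so the counts over the list alone are approximate and can be too high. On simulated lists of 20 genes shifted by 0.1 on the log2 scale, cameraPR found 100% at P8, 70% at P12 and 90% in ovary. It called at most 2% of unchanged lists. The test against matched random lists called at most 4% of them at P8 and in ovary and 8% at P12. The simulated lists held genes drawn at random. So these rates do not cover real lists, whose genes can move together. The p-values of the lists measure spread across genes, not between animals.

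Enriched m6A features had adjusted p below 0.05 and a log2 fold above 1. Fisher's exact test was one-sided for chromosomes and two-sided for overlaps and for the m6A set. For Bind-N-Seq the p-values were adjusted here by the Benjamini-Hochberg method, log2 folds were averaged by base and position, and motifs are given as medians over their 9-mers. Named genes were, in each knockout comparison, Ythdc2, the 10 largest rises and the 10 largest falls among genes with adjusted p below 0.05 and a mean log2 count (in CPM, over the sum of a table) of at least 1, and up to 4 members of each fixed list with the smallest p. For m6A they were the 10 largest enrichments with a mean log2 CPM of at least 3, Ythdc2, and up to 4 members of the m6A and the meiotic lists. For Bind-N-Seq they were the 10 highest and the 5 lowest 9-mers and the fixed motifs. The part of the rule asking that all knockout libraries lie beyond all controls could not be applied, clone names were counted but not named, and members named beyond the rule were chosen after their values were seen. Sums of mean normalized counts were 42229589, 37066681, 23754190 and 24879917 for P8, P12, ovary and m6A, of which exons took 44.6%, 51.1%, 33.6% and 74.0%. The totals of single libraries are unknown, so no counting intervals are given. Alternatives covered other thresholds, floors, introns, other tests of the lists and other summaries of the 9-mers, most of them added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.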

Results

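The series asked what loss of Ythdc2, which encodes an RNA helicase with a YTH domain that binds N6-methyladenosine (m6A), did to transcripts of the mouse germline. It held 14 total RNA libraries of knockout and control gonads, 10 libraries of m6A immunoprecipitation from control testes, and 8 libraries of RNA Bind-N-Seq, a binding assay in which the YTH domain of human YTHDC2 selected RNAs from a random pool. Testes at postnatal day 12 (P12) came as 3 knockout and 3 heterozygous libraries, testes at P8 as 2 knockout, 1 heterozygous and 1 wild-type library, and newborn ovaries (P0) as 2 knockout and 2 heterozygous libraries. The m6A libraries paired immunoprecipitate with input, 1 of each at P8, 2 of each at P12 and 2 of each at P20. Bind-N-Seq had 4 libraries with the YTH domain and 4 with beads alone. The mouse values were the authors' own comparisons of genes, so the spread between replicates is not given at each value. The mean normalized counts of all features summed to 42229589 at P8, 37066681 at P12, 23754190 in ovary and 24879917 in the m6A table.

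In the P12 testis, genes of meiotic prophase I were lower in the knockout. The authors' deposited table gave Spata22, whose product binds DNA during meiotic recombination, a log2 fold change of -1.62 (adjusted p = 1.09e-21). The meiotic cohesin gene Rad21l fell by 1.24 on the log2 scale in the authors' deposited table (adjusted p = 3.53e-15). Ccdc79, also named Terb1, which tethers telomeres to the nuclear envelope, stood at -1.11 in the authors' deposited table, and the crossover gene Msh5 at -1.11 (adjusted p = 1.00e-10 and 5.77e-10). Of the 40 measured genes of meiotic entry and prophase I, 24 fell and 0 rose. The other 16 did not pass or, like Meiob, had no adjusted p, and 32 passed when adjusted over the list alone. The list had a median log2 fold of -0.56, with 33 genes below 0, and lay lower than the other genes (limma, adjusted p = 1.5e-78). Synapsis genes were among the falling members, with Sycp2 at -0.88 and Sycp3 at -0.66 in the authors' deposited table (adjusted p = 5.23e-07 and 0.00407). So were genes of recombination, with Prdm9 at -0.87, Spo11 at -0.85 and Dmc1 at -0.69 in the authors' deposited table (adjusted p = 1.73e-07, 2.75e-05 and 0.000109). Meiob, a partner of Spata22, had a fold of -1.64 without an adjusted p in the authors' deposited table.

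The 7 members of the meiotic list above 0 in the P12 testis did not pass in exons. Per the authors' deposited table, Stra8, which retinoic acid induces at meiotic entry, had an exon log2 fold of 0.39 that did not pass (adjusted p = 0.187), while its introns rose by 0.60 (adjusted p = 0.0173). Rec8, Mlh3, Tex11, Mnd1, Rec114 and Tex15 were the others, with folds of 0.15, 0.14, 0.13, 0.08, 0.07 and 0.04 in the authors' deposited table. Meioc, a gene of meiotic entry whose product works with YTHDC2, had a fold of -0.29 that did not pass either (adjusted p = 0.577) in the authors' deposited table.

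Across all genes of the P12 testis, 122 were lower and 15 higher in exons. Ythdc2 itself was at -1.29 (adjusted p = 9.87e-25) in exons and -0.34 (adjusted p = 0.455) in introns in the authors' deposited table. The largest falls outside the meiotic list in the authors' deposited table were Mtl5 at -1.87, Rad51ap2 at -1.80, Zfp541 at -1.69, Ccnb3 at -1.62 and Kctd19 at -1.59, with adjusted p of 1.24e-32 for Mtl5, 1.55e-27 for Rad51ap2, 8.87e-30 for Zfp541 and 9.02e-25 for Ccnb3. Zfp541 and Kctd19 encode partners in a chromatin complex of spermatocytes, and Ccnb3 a cyclin. Inca1 at -1.34 and Fbxo47 at -1.13 also fell in the authors' deposited table. Cyp17a1, which makes androgens in Leydig cells, had the largest named rise, 0.76 (adjusted p = 0.000122), in the authors' deposited table. It was followed by Gsta2 at 0.59, Slc38a1 at 0.52 and the cystine transporter Slc7a11 at 0.51 in the authors' deposited table (adjusted p = 0.0162 for Gsta2 and 0.0444 for Slc7a11). Cox7b at 0.49, Asah1 at 0.48, Prkar2b at 0.45, Gnb5 at 0.45, Cd52 at 0.42 and Rps3a1 at 0.41 also rose in the authors' deposited table.

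Stromal and Leydig genes of the P12 testis leaned upward. The peritubular and stromal list had a median log2 fold of 0.16, with 12 of 16 genes above 0 (adjusted p = 0.00446) and 0 members called over all genes or when adjusted over the list alone. The Leydig cell list had a median of 0.10, with 11 of 14 above 0 (adjusted p = 0.00126). There 1 member, Cyp17a1, rose, and 3 passed when adjusted over the list alone. The endothelial list had a median of 0.09, with 12 of 14 above 0 (adjusted p = 0.0463), but did not pass against matched random lists (0.183) or at a mean count of 50 (0.0551). Mitotic cell cycle genes had a median of 0.12 with 23 of 34 above 0 and did not pass (adjusted p = 0.0512). Within this list the authors' deposited table had Ccna2, a cyclin of S phase and mitosis, higher at 0.40 and the checkpoint kinase gene Bub1 lower at -0.44 (adjusted p = 0.0345 and 0.0427), and 3 members passed when adjusted over the list alone. The germ cell and piRNA list had a median of -0.09 with 19 of 24 below 0 (adjusted p = 0.00446). Its member Mybl1, a transcription factor of spermatocytes, fell by 0.54 (adjusted p = 0.0144) in the authors' deposited table, and 2 members passed when adjusted over the list alone.

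Other lists at P12 did not pass as groups. Medians were -0.02 for undifferentiated spermatogonia (adjusted p = 0.564), -0.06 for later spermatocytes and spermatids (0.503), -0.04 for Sertoli cells (0.543), 0.07 for erythroid genes (0.538), -0.05 for oocyte genes (0.564), -0.02 for m6A writers, erasers and readers (0.564), 0.02 for p53 response genes (0.720) and -0.04 for cytoplasmic RNA decay (0.343). Differentiating spermatogonia had a median of -0.01 but a mean of 0.04 and a test upward (0.543), macrophages a median of 0.01 but a mean of -0.01 and a test downward (0.902), and pregranulosa genes a median of -0.03 but a mean above 0 and a test upward (0.902). Adjusted over the list alone, 1 differentiating spermatogonia gene, 1 oocyte gene, 1 p53 gene and 2 RNA decay genes passed. Over all genes, the p53 target Sesn2 at -0.46 and the decapping enzyme gene Dcp2 at -0.38 fell in the authors' deposited table (adjusted p = 0.00651 and 0.0376).

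**Figure D1:**
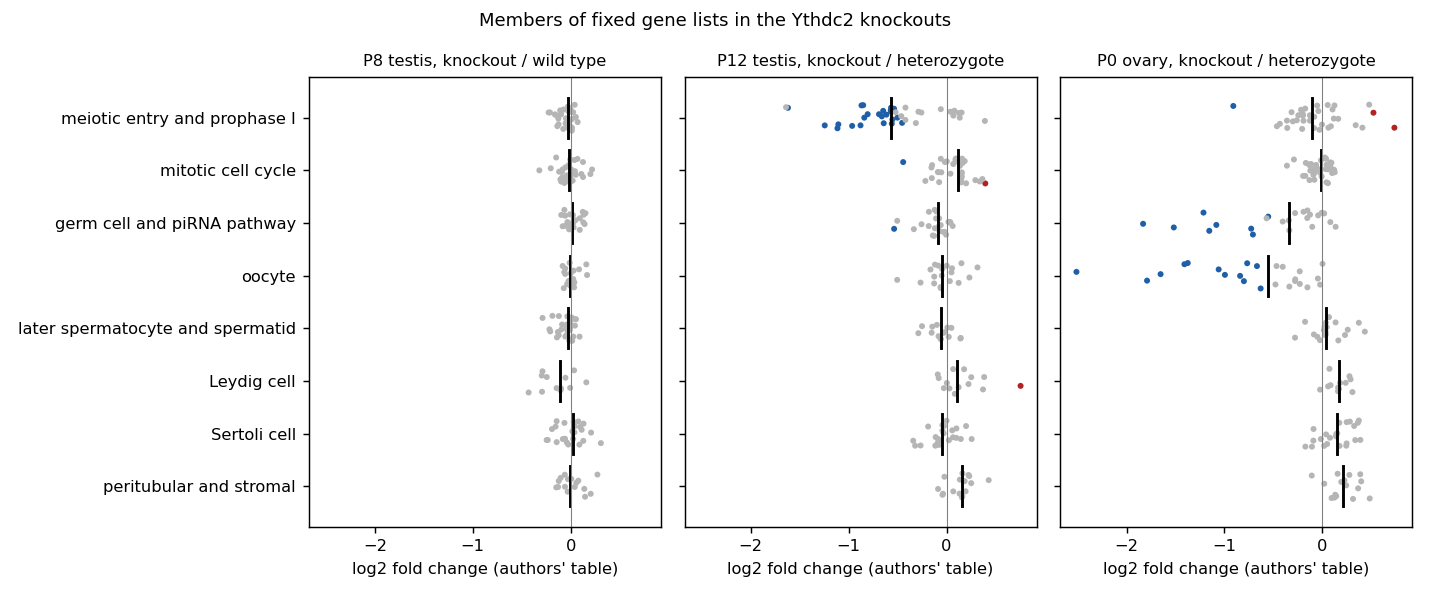
Log2 fold changes (x axis) of the members of 8 fixed gene lists (y axis) in P8 testis, P12 testis and P0 ovary, from the authors' deposited table; each point is a gene, blue if lower and red if higher at adjusted p below 0.05, gray otherwise, and each black bar is the list's median. Meiotic genes had a median of -0.56 in P12 testis and oocyte genes a median of -0.55 in P0 ovary.

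Introns moved with exons in the P12 knockout. Of the genes with lower exons, 111 had introns with a mean count of at least 10, all 111 introns had folds below 0, and 58 of them were called lower themselves. Their median log2 fold was -0.64 in exons and -0.60 in introns, and the median of the difference between them was -0.11. For the meiotic list, 37 of 40 introns were below 0, with 20 called lower and 1, that of Stra8, called higher. In the ovary, 47 genes with lower exons had measured introns, and there the medians were -0.84 in exons and -0.34 in introns, with a median difference of -0.51. Of these 47 introns, 43 were below 0 and 15 were called lower. The genes were picked for their lower exons, which by itself can widen the gap between exons and introns. Over the 24 ovary genes with mean counts of at least 100 in both, the median difference was -0.46. Whether the gap in ovary reflects a change of exons alone was not tested.

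**Figure D2:**
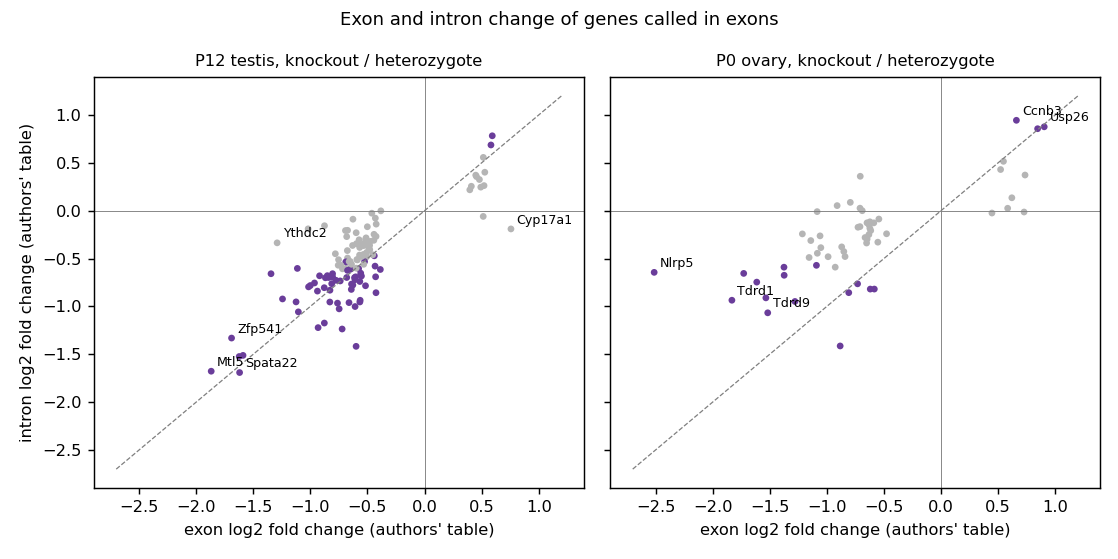
Exon (x axis) against intron (y axis) log2 fold changes of the genes called in exons, in P12 testis and P0 ovary, from the authors' deposited table; purple points have introns that pass too, gray points do not, and the dashed line marks equal change. Points lay near the line in P12 testis (median difference -0.11 for lower genes) and above it in P0 ovary (-0.51).

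In the P12 testis 11 of the called genes lay within 5 Mb on chromosome 7, and all 11 were lower. They reached from Samd4b to Gramd1a (28399522 to 31155935, GRCm38), in a window of 135 measured genes, and had a median log2 fold of -0.62. The authors' deposited table had Cox7a1, which encodes a subunit of cytochrome oxidase, at -1.04 and the neighbouring calpain subunit gene Capns1 lower as well (adjusted p = 1.88e-08 and 1.02e-12). Zfp146, Tbcb, Wdr62, Lrfn3, Arhgap33, Sbsn and Lgi4 made up the rest; these genes are named because of their position, seen after the values. All 135 genes of the window had a median of -0.09, against 0.01 elsewhere. In 10000 shuffles of the called genes over all genes the highest number in any 5 Mb was 9, so the permutation p was 0.0001, the smallest possible. In ovary 10 of the genes were measured, with a median of -0.12, and at P8 the median against the wild type was 0.04, with 0 called in either.

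**Figure D3:**
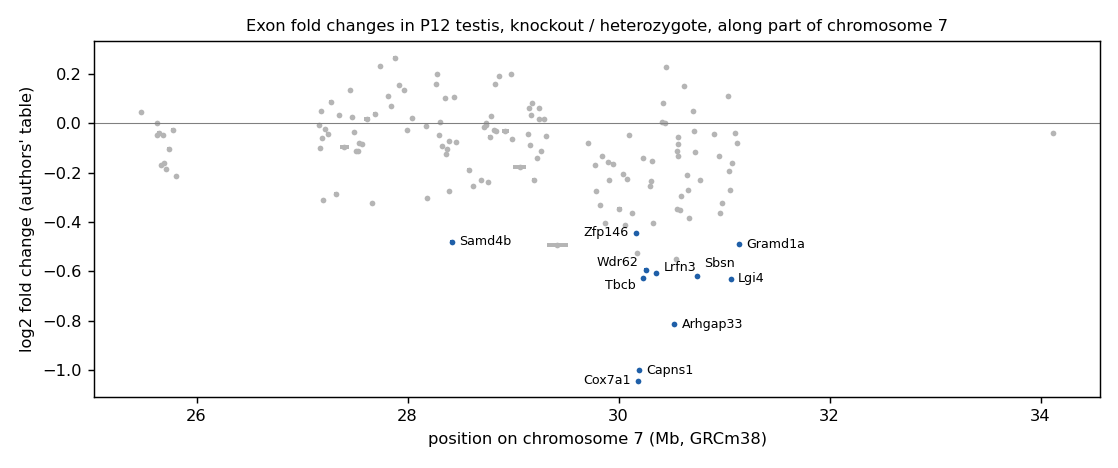
Exon log2 fold changes (y axis) of knockout over heterozygote in P12 testis along part of chromosome 7 (x axis, Mb), from the authors' deposited table; each bar spans a gene, and the named blue genes passed adjusted p below 0.05. The 11 blue genes lay between -0.44 and -1.04.

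In the newborn ovary, oocyte genes and piRNA genes were lower in the knockout. Nlrp5, a maternal-effect gene of oocytes, fell by 2.51 on the log2 scale (adjusted p = 2.21e-44), and the oocyte transcription factors Nobox and Figla stood at -1.79 and -1.41 (adjusted p = 1.72e-22 and 4.20e-14), in the authors' deposited table. Of 24 measured oocyte genes, 12 fell, 0 rose and 12 did not pass, with 17 passing when adjusted over the list alone. The list's median was -0.55, with 23 members below 0 (adjusted p = 2.29e-111). In the authors' deposited table, Dppa3 at -1.65, Lhx8 at -1.38, Kit at -0.84 and Zp2 at -0.67 were among the falling oocyte genes (adjusted p = 1.48e-19, 1.06e-13, 7.58e-05 and 0.000408), while the general germ cell genes Ddx4 at -0.34 and Dazl at -0.15 did not pass.

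The piRNA genes Tdrd1 and Tdrd9, whose tudor-domain products act in transposon silencing, were at -1.83 and -1.52 in the authors' deposited table (adjusted p = 3.08e-25 and 1.23e-15). In the germ cell and piRNA list 8 of 23 genes fell, 0 rose, 10 passed when adjusted over the list alone, and the median was -0.34 with 20 below 0 (adjusted p = 7.62e-49). Mael at -1.21 and Piwil2 at -1.16 were further members that fell in the authors' deposited table. Across all genes 65 were lower and 15 higher. Large falls outside these lists in the authors' deposited table were Alg13 at -1.73, the histone demethylase gene Kdm1b at -1.61, Ccno at -1.57 and Neb at -1.53 (adjusted p = 2.02e-28 for Alg13 and 4.41e-23 for Kdm1b). Ythdc2 had a fold of -0.43 that did not pass (adjusted p = 0.584) in the authors' deposited table.

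In the meiotic list of the knockout ovary, Meioc and Stra8 were higher while the list as a whole lay lower. The authors' deposited table had Meioc at 0.74 and Stra8 at 0.52 (adjusted p = 0.00576 and 0.0266), and, outside the list, M1ap at 0.85, Tex101 at 0.78 and Usp26 at 0.90 (adjusted p = 0.000290, 0.00174 and 5.60e-05). Ccnb3 and Rad51ap2, which were lower in the P12 testis, were higher in ovary at 0.66 and 0.72 (adjusted p = 0.0156 and 0.00512) in the authors' deposited table. C1qtnf3 at 0.73, Tuba3a at 0.64, Aspn at 0.59 and Hmgn2 at 0.58 were the other named rises in the authors' deposited table. In the meiotic list 2 of 36 genes rose, 1 fell and 33 did not pass, and 7 passed when adjusted over the list alone. The cohesin gene Smc1b was the member that fell, at -0.91 (adjusted p = 1.53e-07) in the authors' deposited table. The median of that list was -0.11 with 24 below 0 (adjusted p = 0.0347), while 26 of its 32 measured introns were above 0 with a median of 0.10.

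The stromal, Sertoli, Leydig and pregranulosa lists of the ovary leaned upward. Medians were 0.21 for peritubular and stromal genes with 15 of 16 above 0 (adjusted p = 1.14e-07), 0.15 for Sertoli cell genes with 18 of 23 above 0 (4.41e-05), 0.17 for Leydig cell genes with 11 of 12 above 0 (0.000433) and 0.08 for pregranulosa genes with 14 of 19 above 0 (0.00459). No member of these passed over all genes, and 3 of the stromal list passed when adjusted over the list alone. In the list of differentiating spermatogonia, which shares Stra8, Kit and Sohlh1 with other lists, 1 of 11 genes rose and 3 fell, 5 passed when adjusted over the list alone, and the median was -0.01 (adjusted p = 2.2e-06). The falling members, Sohlh1 at -1.06, Uchl1 at -0.93 and Kit at -0.84 in the authors' deposited table, are also active in oocytes or other germ cells, and the list did not pass on ranks (adjusted p = 0.365) or against random lists matched on mean count (0.637). The p53 list had a median of -0.05 (adjusted p = 0.0186) but did not pass on ranks (0.177) or against matched lists (0.149). In it 2 members, the oocyte quality-control gene Trp63 at -0.88 and Aen at -0.62, fell in the authors' deposited table, the same number as when adjusted over the list alone.

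The remaining ovary lists did not pass. Medians were -0.02 for mitotic genes (adjusted p = 0.258), 0.03 for undifferentiated spermatogonia (0.234), 0.03 for later spermatocytes and spermatids (0.108), -0.03 for macrophages (0.292), -0.11 for erythroid genes (0.135) and -0.02 for RNA decay (0.234). The endothelial median was near 0 (0.438), and m6A writers, erasers and readers had a median of 0.02 but a mean of -0.01 and a test downward (0.764).

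In the P8 testis few genes passed, and 6 of the 7 called against the wild type lay on chromosome 1. The renin gene Ren1 at 0.99 and Sft2d2 at 0.90 were among those higher in the authors' deposited table (adjusted p = 3.63e-05 and 0.000336). Etnk2 at 0.87 and Acadl at 0.81 were higher and Wdfy1 at -0.77 lower in the authors' deposited table (adjusted p = 0.000527, 0.00531 and 0.0136). The call on another chromosome was the ribosomal protein gene Rpl21, which has many pseudogene copies, at 0.89 (adjusted p = 0.000268) in the authors' deposited table. Chance would place 0.403 of the 7 calls on chromosome 1 (one-sided Fisher's exact test, adjusted p = 5.01e-06). The 6 genes were spread from Acadl at 66830839 to Sft2d2 at 165174341 (GRCm38), and the most in any 5 Mb was 2 (permutation p = 0.114). The median fold of the 6 genes was 0.88 against the wild type, 0.46 against the heterozygote and 0.41 in the heterozygote against the wild type. Ythdc2 had a fold of -0.50 against the wild type and -0.24 against the heterozygote at a mean normalized count of 752, and neither passed (adjusted p of 1) in the authors' deposited table.

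Gene lists were shifted slightly in the P8 knockout against the single wild-type library, with 0 members called over all genes. The list tests set genes against genes, so their p-values do not measure the spread between animals. Lists also differed between the single heterozygous and wild-type libraries, with medians of 0.13 for later spermatocyte and spermatid genes and -0.07 for Sertoli cell genes. A list that passed here therefore does not by itself show an effect of the knockout. Leydig cell genes had a median of -0.10 with 11 of 13 below 0 (adjusted p = 2.19e-06), and undifferentiated spermatogonia genes a median of 0.07 with 15 of 20 above 0 (adjusted p = 0.00406). The stem cell gene Foxo1 at 0.30, Sox3 at 0.28 and Sall4 at 0.25 were members of the latter in the authors' deposited table, and Hsd3b1 at -0.43 and Star at -0.29, which act in steroid synthesis, of the former. Differentiating spermatogonia had a median of 0.08 with 10 of 12 above 0 (adjusted p = 0.0402) but did not pass against the heterozygote (0.0841) or at a mean count of 50 (0.0700). Other lists that passed had medians of -0.03 for meiotic genes with 29 of 40 below 0 (0.0102), -0.03 for later spermatocyte and spermatid genes with 21 of 30 below 0 (0.0102), and 0.03 for p53 genes with 15 of 20 above 0 (0.0305). The p53 list did not pass on ranks (adjusted p = 0.110) or against matched random lists (0.312). When adjusted over the list alone, 1 p53 gene passed and no member of the other lists did.

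The other lists at P8 did not pass. Medians were 0.07 for endothelial genes (adjusted p = 0.0887), 0.06 for macrophages (0.252), -0.02 for mitotic genes (0.273), 0.02 for germ cell and piRNA genes (0.772), 0.02 for m6A writers, erasers and readers (0.772), 0.02 for pregranulosa genes (0.913) and 0.01 for RNA decay (0.913). Sertoli genes had a median of 0.02 but a mean below 0 and a test downward (0.824), peritubular and stromal genes a median of -0.01 but a mean of 0.02 and a test upward (0.913), oocyte genes a median of -0.01 but a mean of 0.01 and a test downward (0.913), and erythroid genes a median of -0.02 and a test downward but a mean above 0 (0.913).

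Spermatid genes differed between the P8 knockout and the heterozygote. The protamine genes Prm2 and Prm1 fell by 1.03 and 0.70 on the log2 scale in the authors' deposited table, Akap4 of the sperm tail fell by 0.73, and Tnp2, a transition protein gene, fell by 0.67. In that comparison 6 of 30 later spermatocyte and spermatid genes fell, 8 passed when adjusted over the list alone, and all 30 were below 0 with a median of -0.15 (adjusted p = 9.16e-42). The heterozygous library was itself higher than the wild-type library for 29 of the 30, with a median of 0.13 (adjusted p = 1.46e-46). Mitotic genes had a median of -0.09 in the knockout against the heterozygote (adjusted p = 5.72e-07) and of 0.06 in the heterozygote against the wild type (adjusted p = 9.88e-07). Sertoli cell genes, which did not pass against the wild type, had a median of 0.04 in the knockout against the heterozygote (adjusted p = 0.00954, and 0.177 against matched lists) and of -0.07 in the heterozygote against the wild type (adjusted p = 3.01e-06). Leydig cell genes had a median of -0.12 against the heterozygote (adjusted p = 2.16e-05), undifferentiated spermatogonia genes 0.06 (0.00749), meiotic genes -0.04 (0.0102) and p53 genes 0.04 (0.0429, and 0.114 against matched lists). In the heterozygote against the wild type, germ cell and piRNA genes and stromal genes had medians of 0.05 each (adjusted p = 0.00141 and 0.00505). The wild type and the heterozygote were 1 library each, so neither control gave a spread of its own.

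The called genes of the comparisons scarcely overlapped. Ccnb3 and Rad51ap2 were the 2 genes lower in P12 testis and higher in P0 ovary, where 0.115 were expected among the 14187 genes in both (Fisher's exact test, p = 0.00575). No gene was lower in both, with 0.446 expected, and Slc7a11 was higher in testis and lower in ovary. The 122 genes lower at P12 had a median fold of -0.01 at P8 against the wild type, with 64 below 0, and of -0.04 against the heterozygote, with 80 below 0. Across genes, which are not independent replicates, Spearman's rho between the P12 and P8 folds was -0.30 against the wild type and -0.31 against the heterozygote, and between P12 testis and P0 ovary it was 0.02. Whether an effect differed between ages or tissues was not tested.

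In the m6A immunoprecipitate at P8, 3075 of 15807 genes (19.5%) were enriched in exons, with adjusted p below 0.05 and a log2 fold above 1, and 2712 (17.2%) were depleted. Rab20 had the largest enrichment, 3.56 (adjusted p = 2.01e-41), followed by Cxx1b at 3.52, the transcription factor gene Sox1 at 3.49, Zfp708 at 3.35 and Ascl2 at 3.32, in the authors' deposited table. Further ones in the authors' deposited table were Zfp1 at 3.20, Snrnp35 at 3.08, Sac3d1 at 3.05, Commd5 at 3.01 and Zfp772 at 2.98. Ythdc2 itself was depleted at -2.00 (adjusted p = 4.09e-13) in the authors' deposited table. At P12 the columns of the table gave 3282 enriched of 18324 genes (17.9%) and 2910 depleted, and at P20 they gave 2923 of 16646 (17.6%) and 2602 depleted. Only these counts are given at P12 and P20, since the folds there did not line up with the gene names.

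Meiotic transcripts were mostly on the depleted side of the P8 immunoprecipitation. The folds were relative, with a median of -0.01 over genes with a mean count of at least 10. Depleted, here and for Ythdc2, therefore means less signal than the typical gene and does not show a lack of m6A. These P8 values rest on 1 immunoprecipitate and 1 input. Of 40 meiotic genes 20 were depleted and 1 enriched with a log2 fold beyond 1, and 25 passed below 0 and 4 above 0 at any size, with 33 passing when adjusted over the list alone and a median of -1.01 (adjusted p = 0.000300). Ccdc36, also named Iho1, was enriched at 2.06 and Hormad1, its partner on the chromosome axis, depleted at -2.10 in the authors' deposited table (adjusted p = 1.84e-22 and 3.98e-12). Stra8 was at -0.90 and Tex11 at -1.78 in the authors' deposited table (adjusted p = 0.000212 and 4.88e-16). Mitotic genes had a median of -1.14 with 18 of 34 depleted beyond 1 (adjusted p = 0.00158), germ cell and piRNA genes -1.27 with 17 of 24 (0.000300), and differentiating spermatogonia -0.95 with 6 of 12 (0.0117), though not against matched random lists (0.125). The stem cell factors Nanos2 at 2.56, Sox3 at 2.14 and Foxo1 at 1.70 were enriched in the authors' deposited table. Their list of undifferentiated spermatogonia had a median of 0.69 with 7 of 20 enriched beyond 1, which did not pass as a group (adjusted p = 0.0908).

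Genes of the m6A pathway were themselves enriched with a log2 fold above 1 in 6 of 20 cases and depleted beyond 1 in 2. Rbm15b at 2.50, Rbm15 at 2.04, the reader gene Ythdf2 at 1.84, Ythdf3 at 1.69 and the writer subunit gene Wtap at 1.63 were enriched in the authors' deposited table. Their list had a median of -0.08 but a mean of 0.35 and a test upward (adjusted p = 0.392). Other lists that did not pass had medians of -0.35 for later spermatocytes and spermatids (0.117), -0.36 for Sertoli cells (0.531), -0.40 for Leydig cells (0.288), -0.46 for stromal genes (0.372), -0.50 for macrophages (0.507), -1.15 for erythroid genes (0.0547), -0.74 for oocyte genes (0.0826), 0.15 for pregranulosa genes (0.452) and -0.61 for RNA decay (0.0686). Endothelial genes had a median of -0.09 but a mean of 0.17 and a test upward (0.757), and p53 genes a median of -0.04 but a mean of 0.10 and a test upward (0.858). When adjusted over the list alone, 16 of the m6A pathway genes passed, 18 RNA decay genes, 14 later spermatocyte and spermatid genes and 21 germ cell and piRNA genes.

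Genes enriched for m6A at P8 moved little as a group in the knockouts, and whether the shift passed depended on the test. At P8 against the wild type, their median fold was 0.014 higher than that of other genes (limma on the authors' folds, p = 0.0807), at P12 it was 0.007 lower, a difference of -0.007 (p = 0.796), and in ovary 0.001 higher (p = 0.785). Among the 3016 enriched genes measured at P12, 18 were lower and 0 higher in the knockout, against 104 lower and 14 higher of the other genes. For calls in either direction Fisher's exact test gave p = 0.0520. Against random lists matched on mean count the differences at P8 and P12 passed (permutation p = 0.0002, the smallest possible, and 0.00520), though they stayed near 0.01 on the log2 scale. The same set gave a matched p of 0.0002, the smallest possible in these permutations, in the heterozygote against the wild type, where no knockout library was involved.

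On average over 9-mers, the YTH domain favored RNAs with C after the central A. In Bind-N-Seq, 9-mers with C at the next position had a mean log2 fold over bead control 0.40 higher than all 9-mers, those with T (U in the RNA) 0.21 higher, and those with G and A at -0.27 and -0.33. At the position after that, A stood at 0.27 and T at -0.26, and just before the central A, G stood at -0.17 and A at 0.11. The core GGAC had a median fold of 0.828 over its 1024 9-mers, near the 0.774 of all 9-mers. Of its 9-mers 181 were higher and 462 lower, shares close to the 17.3% and 47.2% of all 9-mers. It ranked 26 of 64 such cores, whose medians were computed here from the 9-mers of the authors' deposited table. AAAC had a median of 1.41 with 560 higher and 63 lower, GAAC 1.15, and AGAC 0.869. The highest cores of this length were ATAC at 1.52 and ACAC at 1.46, and among 5-mers ATACA at 2.26, ACACA at 2.21, ATACC at 2.04 and AAACA at 2.01. The DRACH context, the usual site of m6A, had a median of 1.05, next to 1.06 for the other 9-mers with C after the central A, and 0.774 for all 65536.

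The highest 9-mers of the authors' deposited table were CGTCATGCA at 135-fold, TGTTACACA at 124-fold and ACGTAGCGC at 84.6-fold. They were followed there by CGTCATGCC at 76.3, CGTCATGCG at 73.4, CGTCATGCT at 70.2, GCGTAGCGC at 70.1, GTAAACACA at 60.8, TGTTACAAA at 57.7 and CCGTAGCGC at 56.4 in the authors' deposited table. Among these highest 9-mers, those that start with CGTCATGC had T after the central A, and those that end with CGTAGCGC had G. Most of these 10 thus did not have C there, but most of them belong to those groups of nearly identical sequences. This does not extend to the 162 9-mers above 10-fold, many of which had C after the central A, such as AGCTACCTC at 47.3. The lowest in the authors' deposited table were CCCGATCTT at 0.342, TCCGATCCA at 0.348, CCCGAAGGG at 0.351, AGTGATTTC at 0.374 and GTGCAATTC at 0.375. Of all 9-mers, 42271 (64.5%) had the smallest p that 4 against 4 libraries allow in an exact test, 0.0286 (adjusted p = 0.0443), where chance gives 2.86%. Of these, 11307 were higher and 30964 lower. Of the same 42271, 13530 lay above the median fold of all 9-mers and 28741 below it. Their p-values compare the YTH domain with beads, and a difference from that median was not tested. Some of those above the median were thus lower than the bead control. All 9-mers came from the same 8 libraries and are not independent, so the share expected by chance is no test of the 64.5%. Effects of bases at separate positions, added up, accounted for 35.7% of the variance of the log2 folds.

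**Figure D4:**
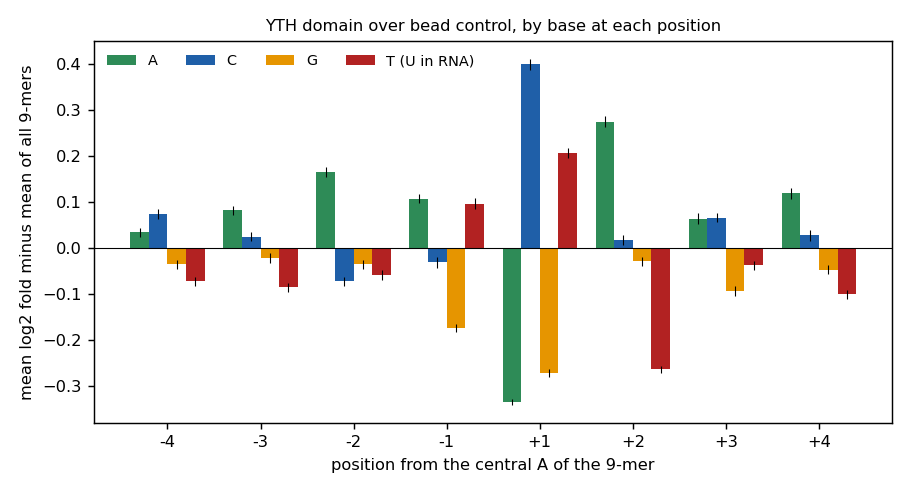
Mean log2 fold of YTH domain over bead control minus the mean of all 9-mers (y axis) by base at each position from the central A (x axis), computed from the authors' deposited table of 9-mers; error bars are 95% intervals across 9-mers, which are not independent replicates. C at the position after the central A stood highest, at 0.40.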

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

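The tests that weigh explanations in this part were chosen only after the results were seen. Signals outside the main comparisons appeared in the heterozygote against the wild type at P8, which served as a comparison of controls. In the authors' deposited table, introns of Cyp17a1 were 1.61 higher on the log2 scale in the heterozygote (adjusted p = 5.13e-13), and those of the potassium channel gene Kcnh1 1.02 higher (adjusted p = 0.00111). Exons of Prm2 and Prm1 were 0.74 and 0.51 higher there in the authors' deposited table (adjusted p = 0.000147 and 0.0226).

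The spermatid transcripts were weighed as a first pattern, since their median was -0.15 in the P8 knockout against the heterozygote and -0.03 against the wild type. Loss in the knockout alone was argued against by the comparison of both controls, in which no knockout library took part and the list's median was 0.13, outside the central 95% of matched random lists. RNA of older testis in the heterozygous library, by cells or by carry-over, is a candidate explanation, as 29 of the 30 tested members were above 0 against the wild type, among them the abundant Hspa2 at 0.15 and Ldhc at 0.07 in the authors' deposited table. An effect of the heterozygous genotype, or a slightly older animal, stays open and untested, since there was 1 library per control.

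Called genes that share a chromosome were a second pattern. Chance placement was argued against by the adjusted p of 5.01e-06 (Fisher's exact test) for chromosome 1 at P8 and by the permutation p of 0.0001, the smallest possible, for chromosome 7 at P12. The chromosome 1 genes share the chromosome but not a window, since the shuffles in 5 Mb did not pass there (2 genes, permutation p = 0.114). On chromosome 1 an effect of the knockout that other comparisons share and a chromosome segment that differs between the mice cannot be told apart, because 0 of the 6 genes passed elsewhere, their P12 median was -0.0316, 5 of the 6 had the same sign in ovary as at P8, and no genotypes were used here. On chromosome 7 the shared effect of the knockout likewise stays open, with a median of -0.12 in ovary and 0.04 at P8 against the wild type, and a segment there was not tested. Ythdc2 lies on chromosome 18, so neither group adjoins the targeted gene.

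Parallel falls of exons and introns in the P12 knockout were the third pattern. Shorter life of mature transcripts alone would leave introns around 0 and was argued against by the 111 of 111 introns with folds below 0. Fewer cells in meiotic prophase is a possible explanation, since 33 of the 40 meiotic genes were below 0. It cannot be told apart from lower transcription within the same cells, because the tables hold whole testes, 7 meiotic genes were above 0 and no cell counts were used here.

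Other signals lay in antisense and repeat features. Antisense reads over introns of Loxl2 stood at -4.23 in the P8 knockout against the wild type (adjusted p = 7.78e-15) and -3.48 against the heterozygote in the authors' deposited table. Antisense reads over introns of Zfp27, on chromosome 7, stood at -2.63 in P12 testis in the authors' deposited table (adjusted p = 2.62e-07). In ovary the authors' deposited table had antisense reads over introns of Syt1 at -4.29 (adjusted p = 3.93e-65). The endogenous retrovirus IAPEY4_I-int was at -0.53 in the P8 knockout against the wild type and at 0.63 in ovary in the authors' deposited table (adjusted p = 0.00340 and 2.48e-18). It did not pass at P8 against the heterozygote, where 0 repeats in sense did. RLTR10B2 was at -0.51 in P12 testis (adjusted p = 0.0379) and RLTR10 at -0.68 in ovary (adjusted p = 5.97e-12) in the authors' deposited table.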

How the results depend on the processing

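Of 392 alternatives run on 122 results, 331 kept direction and side of the threshold or stayed within the set range; 13 had been planned and the others were chosen after the data were examined. The 7 genes called at P8 became 2 in introns, of which fewer were tested. They became 1 when the genes of chromosome 1 were left out of the count, since 6 of the 7 lay there. At adjusted p below 0.01 the 137 genes of P12 became 91 and the 80 of ovary 53, and ovary introns gave 36. Enriched m6A features above a log2 fold of 2 numbered 664 at P8, 629 at P12 and 523 at P20, and above 0 they numbered 5053 at P12 and 4794 at P20, by construction. The difference of the m6A set at P8 passed with the wider set above 0 (0.0158, p = 0.0248 by limma on the authors' folds), against random lists matched on mean count (0.0116) and on count and gene span (0.0144), both at the permutation p of 0.0002, the smallest possible. At P12 it passed against matched lists (-0.00767, permutation p = 0.00520, and -0.0104 with span, permutation p = 0.000800), and with the set above 2 it reversed to 0.0111 at P12 and to -0.00828 in ovary, neither passing (p = 0.576 and 0.990 by limma on the authors' folds). For Bind-N-Seq, medians in place of means moved C after the central A to 0.449 and A to -0.260, and A moved from -0.335 to -0.326 without 9-mers above 10-fold, while means in place of medians moved GGAC from 0.0967 to 0.0339 and DRACH from 0.445 to 0.378. Beyond the genes left out and the thresholds themselves, the cause was not tested. Of 325 alternatives on single lists and exon differences, 286 kept their call. Lost were the calls of p53 genes at P8 and in ovary and of differentiating spermatogonia in ovary by ranks and matched lists, of differentiating spermatogonia at P8 at a mean count of 50 and against the heterozygote and in m6A by matched lists, and of endothelial genes at P12 by matched lists and at a mean count of 50. Calls were gained by mitotic genes at P12, endothelial genes at P8 and erythroid genes in ovary by ranks and matched lists, by macrophages at P8 by matched lists, and in m6A by erythroid genes by ranks and at a mean count of 50 and by oocyte genes at a mean count of 50. With the heterozygote as control at P8, mitotic and Sertoli cell genes passed, the latter upward, and the medians of germ cell and piRNA genes and of pregranulosa genes reversed to -0.0464 and -0.00209, neither passing (adjusted p = 0.107 and 0.834). Within that comparison the Sertoli call was lost by matched lists and the p53 call by ranks, matched lists and a mean count of 50. Gained there were calls of differentiating spermatogonia by ranks, of germ cell and piRNA genes and stromal genes by matched lists, and of macrophages by all 3 alternatives, and in the heterozygote against the wild type that of Leydig genes by matched lists. Against matched lists the median of macrophages at P12 reversed to -0.00257 and that of RNA decay genes to -0.00203 in the P8 knockout against the heterozygote and to 0.00310 in the heterozygote against the wild type, none passing (adjusted p = 0.929, 0.966 and 0.843). No paired analysis was possible because the authors' comparison tables carry no values per library. For the same reason these alternatives of the original plan were not run on the mouse tables: other normalizations (TMM, RLE, totals), other tests on counts, filters and pseudocounts, the replicate block, leaving out libraries, an estimated correlation and the difference of P12 minus P8. The m6A sets from P12 and P20 were not used because their columns did not line up with the gene names. For Bind-N-Seq the replicate block, leaving out libraries, other normalizations and tests, filters and pseudocounts were not run because the 8 columns per library matched no label, and distinct sequences and other k-mer lengths because the file holds 9-mers only. Depth per library is unknown, and folds near the count floor were close to 0, which limits what can be seen among low genes.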

Other observations

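The tests by chromosome, by gene span and on neighbours of 9-mers in this part were chosen after the data were examined. Repeats were part of the m6A signal at P8. In the authors' deposited table the internal parts of the retrotransposons ORR1A0 and ORR1A1 were enriched at 3.40 and 2.98, that of MTA_Mm at 2.70, the satellite MMSAT4 at 2.55 and LTR67B in antisense at 3.69. With a log2 fold above 1, 108 of 915 measured repeats in sense were enriched, as were 512 of 9410 introns. Depleted transcripts included the small RNA Scarna2 at -4.20, the ribosomal protein genes Rps7 at -2.88 and Rps13 at -2.56, and the housekeeping gene Hprt at -2.56 in the authors' deposited table.

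In the P12 knockout, antisense reads of 11 of 85 families of L1 elements were lower and 0 higher. In sense, 0 of 76 L1 families were called, with a median of -0.02, so a change of L1 transcripts is not shown. The 85 families had mean counts of at least 1000 and a median of -0.04, with 58 below 0 and no test of the group, and Lx3B was at -0.20 (adjusted p = 0.000887) in the authors' deposited table. Of the Leydig genes, the intron of the hormone receptor gene Lhcgr fell by 0.73 at P12 (adjusted p = 2.00e-05) while its exons, at 0.03, did not pass (adjusted p = 0.996), in the authors' deposited table. The intron of Cyp17a1 did not pass there (adjusted p = 0.858), and introns of the whole Leydig list were not tested; both genes were picked after their values were seen. The intron of Rspo3, a secreted Wnt agonist, rose by 1.16 (adjusted p = 4.80e-07) in the authors' deposited table. At P8 the introns of Cyp17a1 and Star stood at -2.11 and -0.91 in the knockout against the heterozygote (adjusted p = 3.24e-22 and 0.0134) in the authors' deposited table. Against the wild type they stood at -0.50 and -0.18 and neither passed (adjusted p of 1), and the intron of Cyp17a1 was 1.61 higher in the heterozygote than in the wild type (adjusted p = 5.13e-13), in the authors' deposited table.

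In ovary, called genes were more frequent than by chance on chromosome 6 (11 of 80, adjusted p = 0.0242) and on chromosome X (10 of 80, adjusted p = 0.0160), by Fisher's exact test. At P12 chromosome 7 held 22 of 137 called genes, where 10.4 were expected (Fisher's exact test, adjusted p = 0.0139). Of these, 11 were the genes of the window described above, so this is not a separate observation. At P8 the genes Prm1, Prm2 and Tnp2, neighbours on chromosome 16, made up 3 of the 9 calls against the heterozygote. Across genes, Spearman's rho between the fold and the span of the gene was 0.19 at P8 against the wild type and -0.12 at P12.

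In Bind-N-Seq 162 9-mers were above 10-fold, all at the smallest exact p. The 24 neighbours of each, which differ from it at 1 base, had medians between 0.744 and 6.50 with a median of 2.25, and 160 of the 162 lay above the median of all 9-mers. The top 40 9-mers had a median log2 fold of 5.08, where single bases added up to 0.10. They were picked for their high folds, so an excess over the sum was fixed by the choice.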
